A study of Mus musculus with 60 samples.

How the data were processed

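Circular RNAs (circRNAs), covalently closed RNAs recognised by reads that span a back-splice junction, were sequenced in brain, heart, kidney, liver and spleen of Ftsj1-deficient and wild-type mice. Ftsj1 encodes a tRNA 2'-O-methyltransferase. Per the labels' protocols, frozen tissue was pulverised, RNA was extracted with a phenol-based reagent, ribosomal RNA was depleted, and the remaining RNA was polyadenylated and digested with RNase R, an exonuclease that removes linear RNA. Libraries were then made from fragmented RNA and sequenced on an Illumina NovaSeq. All 6 mice were male and 4 months old, with 3 mice per genotype. The labels state that 4 of the mice are brothers of each other and that the other 2 are brothers too. Of the 4 brothers 2 were wild-type, and of the other 2 brothers 1 was. Each brother group thus held as many Ftsj1-deficient as wild-type mice. Each of the 30 libraries, 1 per mouse and organ, was sequenced in 2 batches because the first gave few reads, which makes 60 samples.

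The values used here are 5 tables of the authors' own comparison, 1 per organ, read here as the comparison of the genotypes. The submitters' processing notes name BWA 0.7.17-r1188, DESeq2 and the mouse build GRCm39, with no roles or order. The circRNA caller, the counting, the model formula and the treatment of the sequencing batches are not given in the sources used here. The name given to the tables by the authors says that low expression was removed in each tissue, and the limit is not given in the sources used here. Per the file headers, each row holds a mean abundance signal, called the mean normalized count below. It was taken as the mean of normalized counts over the libraries of the organ, both genotypes together. Each row also has, per the file headers, a log2 fold change with its standard error (SE). The headers do not name the groups compared, and the fold change was read as being between the genotypes. A test score, the Wald statistic, follows in the deposited tables, and it equalled the log2 fold change divided by its SE in every row. The p-values and adjusted p-values are the authors' own, and recomputing them from the deposited statistics (two-sided normal tail, then Benjamini-Hochberg within the table) gave the same numbers within rounding. A fold change here is therefore the authors' DESeq2 estimate, and the adjusted p belongs to the authors' DESeq2 test.

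Which genotype is the numerator of the fold change is not given in the sources used here. Signs are therefore reported as deposited, positive or negative, and no circRNA is called higher or lower in a genotype. Values per library were not analysed here, so the total reads per sample and the depth behind each value are unknown, and no SD between mice can be given. The SE in the authors' deposited tables is the error used throughout, and 95% intervals are the log2 fold change ± 1.96 SE. If the repeat runs entered the authors' fit as separate samples, these errors would be too small. In liver, 296 circRNAs with a mean normalized count of up to 6.12 have a p-value but no adjusted p in the authors' deposited table, and they count among those tested but could not be called. In all, 43 entries of the deposited tables have no p-value. The p-values rest on a normal approximation with 3 mice per genotype. The SD of the deposited Wald statistics was 0.75 in brain, 0.84 in heart, 0.68 in kidney, 0.76 in spleen and 1.01 in liver. Outside liver they were thus narrower than the standard normal curve behind the p-values. Numbers by chance below are 5% of the tests, so outside liver they may be too high.

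The tests planned before the data were examined needed counts per library and were replaced by a description of the authors' comparison. A circRNA was called at an adjusted p below 0.05 in the authors' deposited table. CircRNAs were named by a rule fixed before the data were examined: those called, those with the smallest p in each direction, the 3 with the highest mean normalized count, and those with an unadjusted p below 0.05 and 1 sign in at least 3 organs. Those with the smallest p over organs or for a difference between organs were added under the same rule. The rule allowed more names per direction and over organs than are given: because the tables hold no gene names, at most 2 circRNAs per direction are named, and over organs only the first or the first 2. CircRNAs are identified by their GRCm39 positions as the tables give them, and the tables hold no gene names. The annotation at hand, GENCODE M21, is for another build, GRCm38, and both ends lay on its exon boundaries for only 73 of 2799 circRNAs. No host gene, exon or intron is therefore given, and the 14 host gene lists fixed beforehand were not tested.

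CircRNAs were matched between organs by both ends. Overlapping circRNAs on a chromosome were joined into loci. Genomic span is the distance from the first to the last base, introns included, so it is not the length of the mature circle. Differences between organs were computed as the difference of the 2 deposited log2 fold changes divided by the root of their summed squared SEs. Means over organs weighted each log2 fold change by the inverse of its squared SE. Both were Benjamini-Hochberg adjusted, were chosen after seeing the data in place of models that need values per library, and treat organs as independent although they come from the same mice. The adjustment, the differences between organs and the weighted means were tested on simulated data that used the deposited SEs. With 200 circRNAs moved in the simulated heart comparison of 664 circRNAs, 58.2% of those moved by 4 log2 units and 29.9% of those moved by 2 were recovered. In the simulated brain comparison of 1853 circRNAs, these shares were 11.9% and 1.01%. The simulated errors took the deposited SEs in full, whereas the deposited Wald statistics outside liver spread less than that.

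A plateau of fold changes was set apart after seeing the data: circRNAs whose absolute log2 fold change exceeded log2 of the mean normalized count by more than 2.5. Alternatives were an adjusted p below 0.1, the 50% of each table with the higher mean normalized counts, a mean of at least 5, adjustment over every circRNA with a p-value, removal of the plateau, and leaving out each organ. Bootstrap intervals of medians used 10000 resamples of circRNAs, and correlations across circRNAs used 100000 permutations. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures used matplotlib 3.10.9.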

Results

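CircRNAs of 5 organs were compared between 3 Ftsj1-deficient and 3 wild-type male mice. The authors' deposited tables listed 1856 circRNAs in brain, 664 in heart, 996 in kidney, 900 in liver and 308 in spleen, after the authors' removal of low expression. Over all organs there were 2799 different circRNAs in 4724 table entries. Depth per library is unknown, and the sign of each fold change is given as deposited because the numerator genotype is not stated.

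The first question was which circRNAs each organ held. Of the 2799 circRNAs, 1821 stood in 1 table, 470 in 2, 202 in 3, 173 in 4 and 133 in all 5. Brain had the most circRNAs of its own, 1101 or 59.3% of its table, against 31.9% in liver, 27.8% in kidney, 18.8% in heart and 10.1% in spleen. Each table was filtered by itself, so a circRNA missing from a table is not shown to be absent from that organ. The circRNAs shared by all 5 organs were among the abundant ones. Their median mean normalized count in the authors' deposited table was 20.2 in brain, where the median of all circRNAs was 3.87, and 28.6 in liver, where it was 8.75. In spleen the 133 shared circRNAs made up 74.6% of the summed mean normalized count in the authors' deposited table, compared with 29.0% in brain. They were 133 of 308 circRNAs in spleen and 133 of 1856 in brain, so these shares depend on the size of the table.

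Abundance ranks were related between organs across shared circRNAs, with Spearman's rho from 0.36 for brain and liver to 0.80 for brain and spleen over the 10 organ pairs. The next highest was 0.60, for heart and spleen. CircRNAs are not independent replicates, and levels were normalized within each table, so levels are not compared in size between organs. The most abundant brain circRNA in the authors' deposited table lay on chromosome 1, 87291826 to 87307730, with a mean normalized count of 364.5. It was followed in brain by chromosome 5, 118731398 to 118731635, at 310.7 in the authors' deposited table. The brain leader on chromosome 1 was also among the 3 most abundant in kidney (127.1) and spleen (129.7) in the authors' deposited tables. The circRNA on chromosome 7, 58890715 to 58896965, led the authors' deposited liver table at 684.2 and was among the 3 most abundant in heart at 80.9. The heart table of the authors' deposited tables was led by chromosome 11, 6263788 to 6267080, at 164.3, and the kidney table by chromosome 5, 89528172 to 89537469, at 145.9. Spleen was led in the authors' deposited table by chromosome 11, 11650205 to 11657904, at 199.5, and its 10 most abundant circRNAs held 32.7% of its summed mean normalized count. The 3 most abundant circRNAs of spleen were also the 3 most abundant of brain, in another order. Whether this likeness lies in the organs or in material shared between libraries was not tested.

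**Figure D1:**
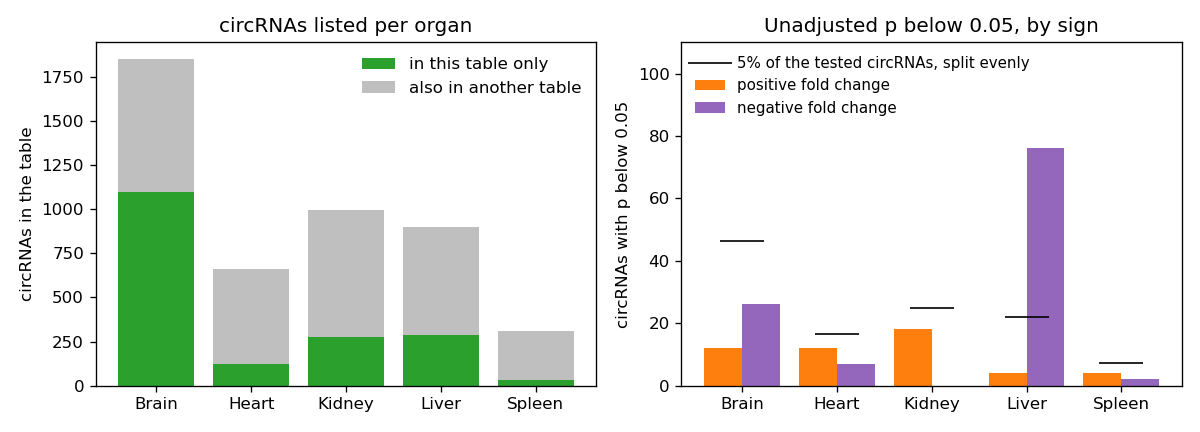
The left panel gives the number of circRNAs in each organ's deposited table, with those found in that table only in green and those shared with another table in grey. The right panel gives the number with an unadjusted p below 0.05 by the sign of the deposited log2 fold change, and the black marks show 5% of the tested circRNAs split evenly between the signs: liver has 76 negative and kidney 18 positive circRNAs.

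Many circRNAs came from shared regions of the genome. The 2799 circRNAs fell into 2126 loci of overlapping circRNAs, and 391 loci held at least 2 circRNAs, 1064 in all. In brain 33.4% of the circRNAs shared their start or their end with another brain circRNA, against 16.2% in spleen. The brain table is larger, 1856 circRNAs against 308, and offers more partners, so this is not shown to be a difference between the organs. The locus with the most circRNAs, 13, lay on chromosome 8 from 78037360 to 78147376. Kidney listed 9 of these, heart 8 and brain 7, and in the authors' deposited tables their log2 fold changes had medians of -0.32, 0.17 and 0.01. Liver and spleen listed 2 each, with medians of -2.61 and -2.41 in the authors' deposited tables, and 1 of those in liver, at -4.95 and on the plateau of fold changes given with the liver comparison, had an unadjusted p below 0.05. Chromosome X, which carries Ftsj1, gave 31 circRNAs, of which 24 were in the brain table. None of the X-linked circRNAs had an unadjusted p below 0.05 in any of the authors' deposited tables, and the median log2 fold change of those in brain was 0.34, with a median SE of 2.09.

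The main question was which circRNAs differed between the genotypes in each organ. In liver, 1 circRNA passed the threshold. It lay on chromosome 17, 79957731 to 79989111, and had a log2 fold change of -7.11 (SE 1.69, adjusted p = 0.0154) in the authors' deposited table, at a mean normalized count of 17.03. Its fold change lay on a plateau described below, where the size is set by the mean, so the size is not an estimate of how strongly the circRNA differed. A pair of other liver circRNAs started at the same base. The one ending at 79966902 was far more abundant, 386.2, and had a log2 fold change of -0.54 (SE 0.38) in the authors' deposited table, with a 95% interval from -1.30 to 0.21. The one ending at 79980002 had -1.79 (SE 1.43) at a mean of 26.3 in the authors' deposited table. In brain, the circRNA ending at 79989111 had a log2 fold change of -0.77 (SE 1.95) in the authors' deposited table.

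Liver also had the most circRNAs at an unadjusted p below 0.05: 80 of 883 tested (9.06%), where 44.1 were the number by chance. Of these, 76 were negative and 4 positive in the authors' deposited table. At an adjusted p below 0.1 there were 17 liver circRNAs, all negative, and 16 of them lay on the plateau described below. After the called one, the smallest p was that of chromosome 5, 66520061 to 66522463, with a log2 fold change of -6.55 (SE 1.80, adjusted p = 0.061) in the authors' deposited table. This circRNA lay on the plateau too, so its size is set by the mean. On the positive side, chromosome 9, 72499033 to 72500642, had 1.76 (SE 0.70, adjusted p = 0.199) and chromosome 1, 87808090 to 87809661, had 2.46 (SE 1.04, adjusted p = 0.268) in the authors' deposited table. The abundant liver circRNAs were estimated more closely. The liver leader on chromosome 7 had -0.03, with a 95% interval from -0.89 to 0.83, in the authors' deposited table. The authors' deposited table gave 0.47 (-0.27 to 1.21) for chromosome 4, 9635901 to 9639347, and 0.36 (-0.55 to 1.26) for chromosome 2, 70600348 to 70617339.

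The negative liver fold changes fell on a sharp plateau. For 135 liver circRNAs the absolute log2 fold change exceeded log2 of the mean normalized count by 2.89 to 3.02, and the next circRNA stood at 1.79. All 135 were negative, and 73 of the 76 negative circRNAs with an unadjusted p below 0.05 were among them, as was the called one. The liver table was divided into 4 groups of 225 circRNAs by mean normalized count. The plateau held 35.6% of the lowest group, 19.1% and 5.33% of the groups between, and none of the highest. The median log2 fold change of the authors' deposited liver table was -0.78 in the lowest group and 0.03 in the highest. Without the plateau no liver circRNA passed the threshold, and the median over the table went from -0.22 to 0.0036. As the plateau held the called circRNA and only negative ones, its removal could not lower the median. Such a plateau is the arithmetic form of a circRNA whose counts lie almost wholly in 1 genotype, and the counts themselves were not analysed here.

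**Figure D2:**
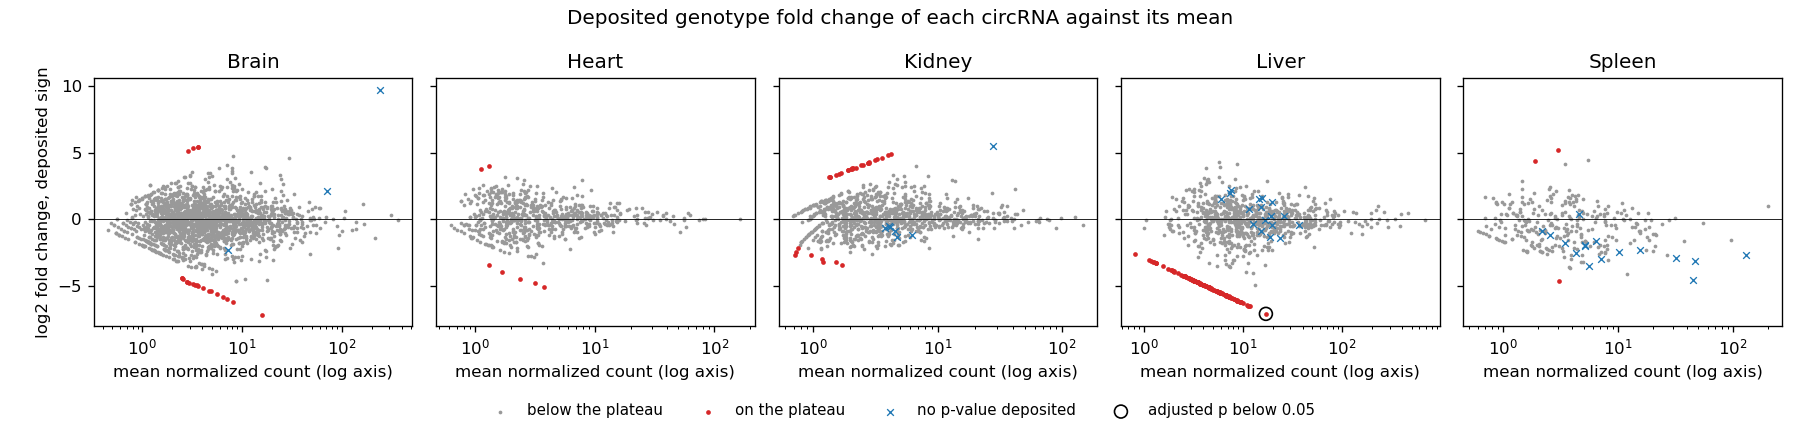
Each point is a circRNA in the deposited table of its organ, with the mean normalized count on a log axis and the log2 fold change as deposited on the vertical axis. Red points lie on the plateau, blue crosses have no p-value, and the black ring marks the 1 circRNA with an adjusted p below 0.05; in liver all 135 red points are negative.

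In brain no circRNA passed the threshold of the authors' DESeq2 test, and 38 of 1853 had an unadjusted p below 0.05 (2.05%), 12 positive and 26 negative, where 92.65 were the number by chance. The smallest p belonged to chromosome 17, 66331071 to 66360086, with a log2 fold change of -7.19 (SE 2.00, adjusted p = 0.589) at a mean of 15.8 in the authors' deposited table. It was followed by chromosome 2, 158224424 to 158225083, at -6.25 (SE 1.90) in the authors' deposited table. The first on the positive side was chromosome 19, 45963406 to 45963714, at 5.32 (SE 1.97), and the next was chromosome 5, 137310136 to 137310495, at 5.11 (SE 2.00), in the authors' deposited table. All 4 lay on the plateau, as did 18 of the 26 negative brain circRNAs. Without the plateau the brain counts were 8 positive and 8 negative, and with a mean of at least 5 they were 8 and 13. The abundant circRNA on chromosome 1 had -0.10, with a 95% interval from -2.23 to 2.04, in the authors' deposited brain table. The authors' deposited table gave 0.31 (-1.94 to 2.55) for the abundant brain circRNA on chromosome 5. The next most abundant, chromosome 11, 11650205 to 11657904, had a log2 fold change of 9.73 (SE 2.21) at a mean of 243.2 and no p-value in the authors' deposited table. The median brain SE was 1.84, so a typical 95% interval reached 3.62 log2 units to each side.

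In heart no circRNA passed the threshold of the authors' DESeq2 test, and 19 of 664 had an unadjusted p below 0.05, 12 positive and 7 negative, where 33.2 were the number by chance. Chromosome 17, 53917892 to 53939746, had a log2 fold change of 2.98 (SE 0.91, adjusted p = 0.638), and chromosome 8, 48352471 to 48373733, had 2.16 (SE 0.74, adjusted p = 0.794), in the authors' deposited table. On the negative side stood chromosome 2, 5057799 to 5059527, at -5.05 (SE 1.63, adjusted p = 0.638) in the authors' deposited table, a plateau circRNA with a mean of 3.77. The next negative one, chromosome 14, 78889121 to 78891236, had -4.82 (SE 1.74) in the authors' deposited table and lay on the plateau too. Heart gave the closest estimates of the 5 organs. The leading heart circRNA on chromosome 11 had a log2 fold change of -0.01, with a 95% interval from -0.45 to 0.43, in the authors' deposited table. The authors' deposited table gave 0.03 (-0.48 to 0.54) for chromosome 10, 120661013 to 120687997, at a mean of 82.7, and 0.01 (-0.58 to 0.61) for the one on chromosome 7. For 20 heart circRNAs the whole 95% interval lay within a 2-fold change either way, against 3 in liver and none in brain, kidney or spleen.

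Kidney gave no circRNA past the threshold of the authors' DESeq2 test, and all 18 of its 989 tested circRNAs with an unadjusted p below 0.05 were positive, where 49.45 were the number by chance. Of these, 14 lay on the plateau. Chromosome 4, 140895024 to 140907843, had a log2 fold change of 4.83 (SE 1.73, adjusted p = 0.999) at a mean of 4.04 in the authors' deposited table. Chromosome 1, 20417435 to 20434455, had 4.88 (SE 1.86) at a mean of 4.24 in the authors' deposited table. The negative circRNAs with the smallest p were chromosome 11, 50192585 to 50199756, at -3.42 (SE 2.16) and on the plateau, and chromosome 19, 4837389 to 4844037, at -2.61 (SE 1.66), in the authors' deposited table. The leading kidney circRNA on chromosome 5 had -0.44, with a 95% interval from -1.84 to 0.96, in the authors' deposited table. The abundant circRNA on chromosome 1 had 0.15 (-1.27 to 1.58), and chromosome 4, 9635901 to 9639347, had 0.10 (-1.32 to 1.52) at a mean of 97.7, in the authors' deposited kidney table.

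Spleen gave none past the threshold of the authors' DESeq2 test, and 6 of 292 had an unadjusted p below 0.05, 4 positive and 2 negative, where 14.6 were the number by chance. Chromosome 1, 181653187 to 181659797, had 5.18 (SE 1.90, adjusted p = 0.998) and chromosome 2, 24703539 to 24715079, had -4.67 (SE 2.02, adjusted p = 0.998), in the authors' deposited table. Next on either side were chromosome 11, 70765572 to 70775794, at 4.41 (SE 1.86), and chromosome 1, 138967738 to 138969781, at -4.12 (SE 1.97), in the authors' deposited table. Of these 4, the first on each side lay on the plateau. Only 35.7% of the spleen circRNAs had a positive log2 fold change in the authors' deposited table, 110 against 198 negative, with a median of -0.55. The median SE of single circRNAs was 1.95, which is not the error of that median. In the highest of 4 abundance groups of spleen the median was -0.76 (bootstrap interval over circRNAs from -1.35 to -0.38). All circRNAs share the same libraries, so this shift was not tested against the spread between mice. The leading spleen circRNA on chromosome 11 had 0.97, with a 95% interval from -2.02 to 3.96, in the authors' deposited table. The abundant circRNA on chromosome 1 had -2.72 (SE 1.38) and no p-value, and the abundant one on chromosome 5 had -1.59 (-4.31 to 1.13) at a mean of 96.6, in the authors' deposited spleen table. In heart that circRNA on chromosome 1 had -0.95 (95% interval from -1.73 to -0.17, adjusted p = 0.996 in the authors' DESeq2 test). In liver it had -0.59 (SE 0.62) in the authors' deposited table.

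It was then asked whether the organs shared a genotype effect. The circRNA on chromosome 11, 70765572 to 70775794, had an unadjusted p below 0.05 with a positive sign in 3 organs. Its log2 fold changes in the authors' deposited tables were 4.63 (SE 2.26) in brain, 3.26 (SE 1.46) in kidney and 4.41 (SE 1.86) in spleen, and heart and liver did not list it. The weighted mean was 3.89 (SE 1.02), and it did not pass after Benjamini-Hochberg adjustment over the 505 circRNAs with a p-value in at least 3 tables (adjusted p = 0.0727). None of the 505 passed, and 11 had an unadjusted p below 0.05. When p-values and signs were shuffled among the circRNAs within each organ, 7 of 1000 shuffles gave any circRNA below 0.05 with 1 sign in 3 organs. The organs came from the same mice, which these shuffles and weights leave out. The circRNA on chromosome 7, 97893156 to 97915454, was negative in brain (-3.24, SE 1.57) and heart (-3.30, SE 1.58) and at -0.13 (SE 1.97) in kidney in the authors' deposited tables.

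Among the 120 circRNAs with a p-value in all 5 organs, none passed for the mean over organs, with 5 below an unadjusted p of 0.05 and 6 by chance. The smallest p was that of chromosome 12, 69870196 to 69872557, positive in all 5 organs with a weighted log2 fold change of 1.20 (SE 0.49, adjusted p = 0.934). For these circRNAs a typical 95% interval of the weighted mean reached 0.945 log2 units to each side. Of the 133 circRNAs listed in all 5 organs, 13 had 1 sign throughout, where 5.89 were the number for independent signs. The same mice gave all 5 organs, so signs need not be independent and the excess is not shown to come from genotype. Across shared circRNAs the Pearson correlation of log2 fold changes between organs ran from -0.11 for brain and kidney to 0.35 for brain and spleen, and Spearman's rho from -0.12 to 0.33 over the same 10 pairs.

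Differences between organs were tested for 3341 pairs of estimates. None passed the adjustment, and 115 had an unadjusted p below 0.05 (3.44%), fewer than the 167 by chance. Of these 115, 84 involved liver, as did 1405 of the 3341 tests. The smallest p was that of the circRNA on chromosome 4, 140895024 to 140907843, between kidney (4.83) and liver (-6.21, SE 2.02) in the authors' deposited tables. That difference was 11.04 log2 units (SE 2.66, adjusted p = 0.112), and both estimates lay on the plateau of their organ. The same circRNA had 2.24 (SE 2.01) in brain and -0.92 (SE 2.14) in spleen in the authors' deposited tables.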

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

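All tests in this part were chosen after the results were seen. The entries below have a fold change beyond 1.96 SE but no p-value in the authors' deposited tables, so no test counts them, although they enter the medians and the counts of signs over whole tables. In DESeq2 a missing p-value can mark a feature in which 1 library has an extreme count, and the counts per library were not analysed here.

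The circRNA on chromosome 11, 11650205 to 11657904, had a brain log2 fold change of 9.73 (SE 2.21) at a mean normalized count of 243.2, among the 3 highest in brain, in the authors' deposited table. It led the spleen table, and in the authors' deposited tables its log2 fold changes were 0.97 in spleen, 1.34 in liver, 0.72 in kidney and 0.46 in heart. A candidate source is spleen material in brain libraries of 1 genotype. Levels were scaled within each table, so the ratio of its brain to its spleen mean, 1.22, was used only to set how much of the spleen profile the brain table would have to hold. At that amount the other 20 most abundant spleen circRNAs, all listed in brain, would have a median brain log2 fold change of 1.40. Their observed median was 0.25 (bootstrap interval over circRNAs from -0.0014 to 0.722), and each of the 20 lay below its own expected value. All 20 were measured in the same brain libraries, an error the bootstrap leaves out, and their median brain SE was 1.19. These 20 fold changes were thus lower than spleen material at that level would give, but it is not excluded. Other brain values could go with material from another organ. Brain circRNAs listed in no other organ had a median log2 fold change of -0.36, against 0.08 for those shared with another organ. The 133 circRNAs listed in every organ had a brain median of 0.64, and 99 of them were positive. These differences were not tested. Spleen material, a single aberrant library and a change of this circRNA alone stay open, and no biological explanation was tested.

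In spleen, 3 abundant circRNAs met the same condition with negative signs. Their log2 fold changes in the authors' deposited table were -2.72 on chromosome 1, 87291826 to 87307730, -3.16 on chromosome 3, 51215471 to 51233456, and -4.58 on chromosome 1, 178150699 to 178152878. The first of these had -0.95 (SE 0.40) in heart, -0.59 in liver, -0.10 in brain and 0.15 in kidney in the authors' deposited tables. Of the 16 spleen circRNAs without a p-value 15 were negative, with a median log2 fold change of -2.39 for the 16 against -0.46 for those with a p-value in the authors' deposited table.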

How the results depend on the processing

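An adjusted p below 0.1, the higher means for the counts of called circRNAs and for single circRNAs, a mean of at least 5 for the number of circRNAs listed, and leaving out an organ were planned. A mean of at least 5 for called or single circRNAs, adjustment over every p-value, removal of the plateau, and the settings applied to the counts by sign and the medians were chosen after the data were seen. The liver count of 1 changed circRNA became 17 at an adjusted p below 0.1, 5 in the 50% with the higher mean normalized counts, where fewer circRNAs are tested, and 0 without the plateau, which removes the called circRNA itself. It stayed at 1 with a mean of at least 5 and with adjustment over every p-value. Brain, heart, kidney and spleen stayed at 0 under these settings, as did the mean over organs and the difference between organs when each organ was left out. Outside liver every circRNA with a p-value already had an adjusted p. Adjustment over every p-value therefore repeated the main result there and could not change it. Such repeats are counted below as keeping the result. The liver median log2 fold change of -0.22 changed sign to 0.0036 without the plateau. The direction of that change was fixed, since the plateau was defined by the size of the fold change and its 135 liver circRNAs were all negative. With a mean of at least 5, where fewer enter, the 2799 circRNAs became 1279 and the 133 in all 5 tables became 60. Over all 134 alternatives of 44 results, 111 kept the result, 21 moved it, 1 brought a liver circRNA past the threshold (chromosome 5, 66520061 to 66522463, adjusted p = 0.0453 in the 50% with the higher means, against 0.061) and 1 reversed it.

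No paired analysis was possible because the tables give 1 comparison per organ and no value per library. For the same reason leaving out a mouse, the brother groups, other normalizations or tests, single sequencing batches, other splits of the mice, total junction reads and pseudocounts were not run, and host gene sums and lists were not run for want of gene names in the build of the tables. The size of the errors limits what can be seen, with typical 95% intervals from 3.05 log2 units to each side in heart to 4.04 in liver. What part depth has in this is unknown, and heart had the lowest median mean normalized count (2.78) and liver the highest (8.75).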

Other observations

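All tests in this part were chosen after the results were seen. The plateau was not specific to circRNAs found in liver alone: 31.1% of the 135 plateau circRNAs stood in the liver table only, against 32.0% of the other liver circRNAs. In the other organs, medians of the deposited log2 fold changes are given for the plateau circRNAs beside those of the other circRNAs shared with liver, and their differences were not tested. In the authors' deposited tables the 61 also listed in brain had a median of -0.25 against 0.35, and the 20 in spleen -0.43 against -0.80. The 71 in kidney had 0.28 against 0.03 and the 39 in heart 0.25 against 0.03 in the authors' deposited tables. None of them was negative with an unadjusted p below 0.05 in another organ. The whole tables held few such circRNAs, 26 in brain, 7 in heart, 2 in spleen and none in kidney, so this says little. Kidney and liver shared 458 circRNAs, and 1 of them was on the positive plateau in kidney and the negative plateau in liver, where 0.465 was the number by independence (Fisher's exact test, p = 0.397).

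The liver plateau circRNAs spanned more of the genome, with a median of 9412 bases against 3649 for the other liver circRNAs. Fewer reads in the liver libraries of 1 genotype could leave rare circRNAs uncounted there, and such a loss was taken to depend on abundance alone. Within 12 bins of abundance, plateau circRNAs exceeded the others in span by a median of 1.14 log2 units. That was beyond all 1000 shuffles within bins (-0.86 to 1.06). The bins rest on the mean over both genotypes, which near absence in 1 genotype lowers, so abundance was not fully matched. Shuffles also treat overlapping circRNAs as independent. Plateau circRNAs thus had larger spans at a like mean, which does not decide whether fewer reads are the whole cause. One scaling factor per library would move every circRNA alike. A common shift as large as the least negative plateau value, -2.61, would then show in abundant circRNAs too. In the highest of 4 abundance groups, which holds no plateau circRNA, the median was 0.033 (bootstrap interval over circRNAs from -0.14 to 0.19). The plateau is therefore not a shift of that size common to all deposited fold changes. Plateau sizes are set by the mean, so a smaller common shift behind the plateau was not tested this way. Normalization can itself centre the abundant circRNAs, so a difference between libraries before normalization cannot be excluded this way. A loss of larger circles by breakage or digestion stays open: in the highest abundance group span and log2 fold change had a Spearman's rho of -0.25. The mature lengths needed to decide are not known here. Fewer reads, as part or the whole of the cause, stay open too, as does an effect of the genotype, untested because the sign and the libraries are not given.

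The relation of span to log2 fold change depended on which circRNAs entered. In the highest of the 4 abundance groups of each organ, Spearman's rho across circRNAs, which are not independent replicates, was -0.17 in brain, -0.25 in liver and -0.36 in spleen, the last over 77 circRNAs (permutation tests, two-sided, Benjamini-Hochberg adjusted over 5 organs, adjusted p = 0.00055, 0.00055 and 0.0025). In kidney it was 0.15 (permutation test, adjusted p = 0.0263) and in heart -0.0044 (permutation test, adjusted p = 0.955). Over whole tables rho was -0.09 in brain, -0.18 in liver, -0.02 in spleen, 0.07 in kidney and 0.10 in heart, so the spleen value is not there over the whole table. The differences between these correlations were not tested.

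A single circRNA mapped to chromosome Y, 1186774 to 1199513, and 1 to the mitochondrial genome, 13774 to 13916. In the authors' deposited tables the former had log2 fold changes of -0.10 (SE 2.06) in brain and 1.84 (SE 1.98) in kidney, and the latter 2.09 (SE 1.87) in heart and 0.02 (SE 1.72) in kidney.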
